A study of Homo sapiens with 60 samples.

How the data were processed

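The data were directional RNA sequencing of A549 cells, a human lung adenocarcinoma line, after 24 h with plant extracts. Per the labels, 60 libraries covered 1 vehicle group and 7 hot-water extracts at 500, 100 and 20 µg/mL: the herbs Menthae Herba and Saposhnikoviae Radix, and the decoctions Saengmaek-san, Guibi-tang, Soyo-san, Okbyeongpung-san and Soshiho-tang. Per the labels the plant material was refluxed in water for 3 h. Per the labels libraries were made from 1 µg of total RNA with an RNA integrity number over 7, using the MGIEasy RNA Directional kit, and sequenced on an MGIseq instrument as 100 bp paired-end reads. The sample labels gave 0.1% DMSO for the vehicle and the description of the series gave 2%. A wortmannin control at 10 µM and ethanol extracts are mentioned in the sources and were not analysed here. The description of the series also stated that extracts with a 20% inhibitory concentration under 500 µg/mL were given at that concentration and at dilutions of it, and that libraries with little RNA were excluded. The labels used here printed 500, 100 and 20 for every extract.

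Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned with STAR 2.7.3a and quantified with RSEM 1.3.3 on the human build hg38, also called GRCh38. The authors deposited RSEM expected counts for 60675 genes in each library. The annotation release, the strandedness setting of the counting step and the method for differential testing were not given in the sources used here. Of all cells of the table, 10.5% were not whole numbers, and all were rounded to whole counts before testing. Every per-sample column of the table was used, and 0 were left aside.

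Gene IDs were matched to symbols with a current table of human gene names (56558 genes), and 497 further genes took the symbol of GENCODE 29. The remaining 3620 genes had no symbol and held 0.0703 to 0.0819% of the counts of a library. Positions and gene types are those of GENCODE 29 on GRCh38. Library totals ran from 18330592 to 35308791 counts. The 57 pairs of libraries inside a group differed by more than sampling noise, with chi-square per degree of freedom of 1.95 to 91.9. Over all 1770 pairs of libraries the lowest was 1.95, with 0 under 1.1, so no library was a copy of another.

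Groups were formed by extract and dose. The vehicle and 6 extracts at 3 doses gave 19 groups of 3 libraries, 57 in all, which shared 1 edgeR 4.0.16 quasi-likelihood fit (R 4.3.3, limma 3.58.1; TMM scaling, filterByExpr by group, robust estimation off). The filter kept 17256 genes. Soshiho-tang had 1 library per dose and was left out of the fit, because no spread can be estimated from 1 library. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these samples. Levels are CPM, counts scaled to the library total, as mean ± SD of 3 libraries. Log2 CPM, not fold changes, used a prior count of 2. Standard errors come from the quasi-likelihood statistic. Adjusted p refers to the Benjamini-Hochberg method within each of the 29 comparisons, and a gene or list was called at an adjusted p under 0.05. The 29 comparisons, the gene lists, the named-gene rule and the alternatives were fixed before the data were examined. They were each extract and dose against vehicle, 500 against 20 within each extract, each decoction at 500 against a herb it contains (Soyo-san and Menthae Herba, Okbyeongpung-san and Saposhnikoviae Radix), and 3 pairs of extracts at 500 that shared a first number in the library name (Menthae Herba and Saposhnikoviae Radix, Saengmaek-san and Guibi-tang, Soyo-san and Okbyeongpung-san). For these 5 pairs the difference of the 500-against-20 changes was also tested; the first 2 of these tests were planned and the other 3 were added after the data were seen.

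Genes are named by a fixed rule. Against vehicle at 500, the 8 highest and 8 lowest fold changes were taken among called genes with a mean of 5 CPM or more in either group, all treated libraries on 1 side of all vehicle libraries, and a symbol that was not a clone or accession name. Against 20 and between extracts the same rule took the 5 highest and 5 lowest. Up to 3 called members with the largest change in the direction of each called list were added. A panel of genes was followed in every extract and dose, among them CYP1A1, CYP1B1, HMOX1, NQO1, HMGCS1, DDIT3, TRIB3, CDKN1A, CXCL8, VEGFA and MKI67. For Soshiho-tang the rule took the 8 highest and 8 lowest log2 ratios among genes with 20 CPM or more whose 500 and 100 libraries both lay outside the vehicle range on the same side. Genes were dropped only from the end of a ranking, apart from items withheld for evaluation, which are not reported here.

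The 31 lists were AhR targets, NRF2 targets, cholesterol synthesis, fatty acid synthesis and LXR targets, ER chaperones and unfolded protein response, ATF4 and integrated stress response, heat shock response, hypoxia and glycolysis, p53 targets, DNA replication and G1/S, mitosis and G2/M, NF-kB and inflammatory cytokines, type I interferon response, metallothioneins and metal response, TGF-beta and mesenchymal genes, lysosome and autophagy, PXR and CAR targets, glucocorticoid receptor targets, PPAR targets and fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded transcripts, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, immediate early genes, circadian clock genes, alveolar type II and lung epithelial genes, complement and acute phase genes, replication-dependent histones, leukocyte markers, fibroblast markers and endothelial markers. They were written from general knowledge and matched by symbol. Lists with 5 or more tested members were tested with camera on log2 CPM at a preset correlation of 0.01, adjusted over all lists and 6 extracts, and again with a correlation estimated from the data and with fry. Counts of list members past FDR 0.05 use the adjustment over all genes, and counts "adjusted over the list alone" use only the members.

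Soshiho-tang was described by log2 ratios of CPM to the vehicle mean with a prior of 0.5 CPM. Its list medians were ranked among 10000 random lists matched on mean expression. Similarity of extracts was the Pearson correlation and Spearman rho across genes of the 500-against-20 log2 fold changes, which share no library between extracts; genes are not independent replicates and no p is given. Simulated unchanged groups that share 3 vehicle libraries were used beside the values against vehicle.

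Alternatives tried were DESeq2 1.42.0 on the same groups, RLE scaling, no filter on low counts, only the 2 compared groups in the fit, the replicate number as a block, and each library left out in turn. A term for a step in the library order, and fits inside each part of that order, were added after the step was seen. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

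The procedure was tested on simulated data. For Menthae Herba 500 against vehicle, counts of 16913 genes were simulated with 200 genes changed. At true changes of 1.25, 1.5, 2 and 4-fold, edgeR called 44, 66, 80 and 96% of the 50 changed genes at each size, and 5 unchanged genes. DESeq2 called 44, 64, 78 and 90%.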

Results

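A549 lung adenocarcinoma cells were sequenced after 24 h with 7 hot-water plant extracts at 500, 100 and 20 µg/mL or with vehicle (60 libraries). The 6 extracts with 3 libraries per dose were Menthae Herba, Saposhnikoviae Radix, Saengmaek-san, Guibi-tang, Soyo-san and Okbyeongpung-san. Soshiho-tang had 1 library per dose. The share of counts from mitochondrially encoded genes differed along the library order. It was 12.3% ± 0.225 (SD, n = 3) in vehicle, 11.9% ± 0.747 in the first 31 libraries of the library order and 16.1% ± 2.26 in the last 29, with extremes of 10.7 and 22.2%. The first principal component held 14.3% of the variance, and the step after the 31st library accounted for 82.1% of it. Vehicle, both herbs and 10 of the 18 Saengmaek-san and Guibi-tang libraries lay before the step. The other 8 and all libraries of Soyo-san, Okbyeongpung-san and Soshiho-tang lay after it. The p-values are from 1 edgeR fit of 57 libraries and 17256 genes. Ranks of genes below hold among called genes of 5 CPM or more that met the naming rule, here called ranked genes, and some rarer genes changed by more.

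**Figure D1:**
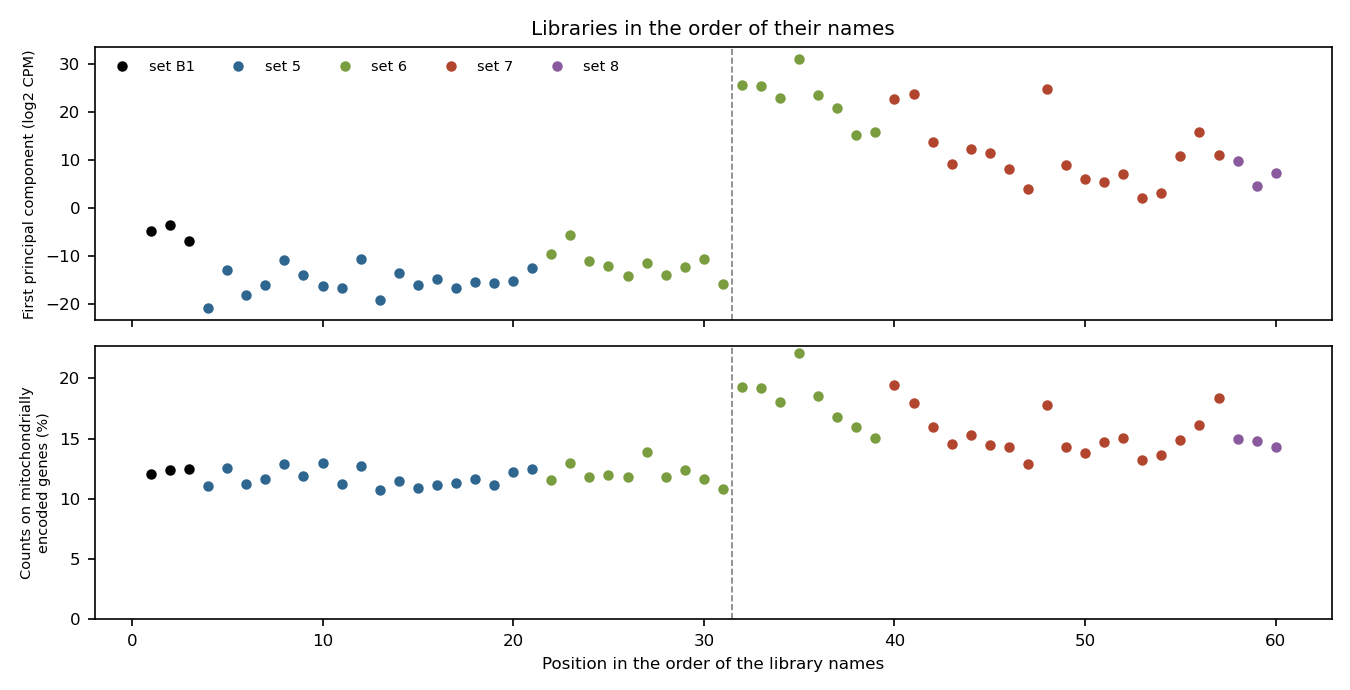
First principal component and mitochondrial share of each library in library order. The step after the 31st library separates the last 29 libraries from vehicle.

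Menthae Herba at 500 raised genes of the aryl hydrocarbon receptor (AhR) response most among the ranked genes. CYP1A1, an oxidising enzyme of foreign compounds (chromosome 15, 74719542 to 74725610), rose with a log2 fold change of 2.84 ± 0.167 (7.26 ± 0.421 CPM against 1.01 ± 0.128, n = 3; adjusted p = 1.73e-17). TIPARP, which encodes a mono-ADP-ribosyltransferase that limits the receptor (chromosome 3, 156673235 to 156706770), rose by 1.29 ± 0.0512 (adjusted p = 6.33e-24), CYP1B1 (chromosome 2, 38066973 to 38109902) by 1.17 ± 0.0426 (215 ± 5.08 CPM against 95.3 ± 0.876; adjusted p = 3.15e-25) and the receptor's repressor AHRR by 1.11 ± 0.117 (adjusted p = 2.82e-09). The long noncoding RNA GACAT2 (1.02), the epithelial transcription factor GRHL3 (0.93), the dehydrogenase DHRS13 (0.81) and the secreted BMP antagonist GREM1 (0.71) rose next. Among the ranked genes the largest falls were those of the orphan nuclear receptor NR4A1 (chromosome 12, 52022832 to 52059507), with a change of -1.35 ± 0.0908 (13.0 ± 1.53 CPM against 33.1 ± 1.11; adjusted p = 2.16e-15), the imprinted noncoding RNA H19 (-1.09), NR4A3 (-1.08) and the small heat shock protein CRYAB (-0.90). Of the genes tested, 577 rose and 592 fell, and 18 rose and 30 fell at least 2-fold. The count of 1169 dropped to 675 without vehicle replicate 2 and to 647 without Menthae Herba 500 replicate 1, and it was 2723 with only the libraries before the step in the library order, where all of these libraries lie.

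By group, 4 of the 8 AhR targets rose at 500 of Menthae Herba (list median 0.59, adjusted p = 2.61e-14, adjusted p = 1.74e-08 with an estimated correlation), while ALDH3A1 (0.03), UGT1A6 (-0.18), STC2 (0.07) and NFE2L2 (-0.03) did not pass. The haem-degrading enzyme HMOX1 rose (0.55 ± 0.0425; adjusted p = 1.81e-13) and NQO1 did not (0.12; adjusted p = 0.322). Of 24 ribosome biogenesis and MYC targets, ODC1 (-0.23), WDR43 (-0.20) and DDX21 (-0.16) fell, 0 rose and 21 did not pass (list median -0.09, adjusted p = 1.61e-04, adjusted p = 0.035 with an estimated correlation). WDR43 lost its call without Menthae Herba 500 replicate 2 (adjusted p = 0.0544), and DDX21 without a filter on low counts (adjusted p = 0.0633). Of 28 ATF4 and integrated stress response genes, 5 rose, among them the serine and gluconeogenic enzymes PHGDH (0.37) and PCK2 (0.45), and 10 rose and 3 fell when adjusted over the list alone (adjusted p = 0.0108, adjusted p = 0.181 with an estimated correlation). Of 22 hypoxia and glycolysis genes, ADM (0.28) and BNIP3L (0.27) rose (list median 0.10, adjusted p = 0.00673, adjusted p = 0.0686 with an estimated correlation), and VEGFA did not pass (-0.07). Of 11 alveolar and lung epithelial genes, the mucins MUC5B (-0.84) and MUC5AC (-0.61) and the keratins KRT18 (-0.29) and KRT8 (-0.27) fell and the lipid transporter ABCA3 rose (0.40) (list median -0.15, adjusted p = 0.00673, adjusted p = 0.122 with an estimated correlation). The fibrinogen chains FGB (-0.40), FGA (-0.27) and FGG (-0.27) fell among 12 complement and acute phase genes (adjusted p = 0.00984, adjusted p = 0.13 with an estimated correlation), and without Menthae Herba 500 replicate 2 this list gave 0.0775. The 26 DNA replication genes lay lower (median -0.05, 2 fell; adjusted p = 0.00545, 0.323 with an estimated correlation). The 24 cholesterol synthesis genes lay higher (median 0.07; 1 rose and 1 fell; adjusted p = 0.0448, adjusted p = 0.557 with an estimated correlation), a call that 4 of the 6 leave-one-out fits lost, with 0.0967 without vehicle replicate 1 as the highest value.

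CYP1A1 and CYP1B1 rose more at higher doses of Menthae Herba. CYP1A1 rose at 100 (1.26; adjusted p = 5.25e-05) and did not pass at 20 (0.32; adjusted p = 0.639), and CYP1B1 rose at 100 (0.41; adjusted p = 2.51e-08) and stood at -0.00 at 20. Against its own 20 dose, Menthae Herba at 500 raised CYP1A1 (2.52 ± 0.167), TIPARP (1.32 ± 0.0521), AHRR (1.19 ± 0.121), CYP1B1 (1.18 ± 0.0428) and GREM1 (0.96 ± 0.111) and lowered NR4A1 (-1.36 ± 0.0920), NR4A3 (-0.98), CRYAB (-0.98), H19 (-0.97) and the growth factor binding protein IGFBP5 (-0.86). In that test 155 genes rose and 265 fell, and of the 420 calls 332 were also called against vehicle, where the libraries at 500 are the same. Their higher genes, chosen for the difference of 500 and 20, had a median log2 fold change against vehicle of 0.09 at 100. The 8 AhR targets were called again (median 0.67, adjusted p = 1.34e-25, 6.13e-12 with an estimated correlation). At the preset correlation the complement and acute phase genes (adjusted p = 0.00101), ER chaperones (adjusted p = 0.00318), alveolar genes (adjusted p = 0.00667), NF-kB genes (adjusted p = 0.0109) and heat shock genes (adjusted p = 0.0207) lay lower. The ATF4 (adjusted p = 0.0109) and NRF2 lists (adjusted p = 0.026) lay higher. With an estimated correlation these 7 lists gave 0.0665, 0.0707, 0.159, 0.0528, 0.655, 0.217 and 0.452. Single libraries ended 4 of these calls: NRF2 targets without 500 replicate 1 (0.113), ATF4 genes without 500 replicate 2 (0.0502), heat shock genes without 20 replicate 1 (0.0518) and NF-kB genes without 20 replicate 2 (0.0887). Against vehicle, 168 genes passed at 100 and 66 at 20, and leave-one-out fits gave 50 to 95 and 16 to 44.

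Saposhnikoviae Radix at 500 moved the same receptor's genes by less. CYP1A1 rose by 1.19 ± 0.182 (2.26 ± 0.521 CPM against 1.01 ± 0.128, n = 3; adjusted p = 0.000103), CYP1B1 by 0.48 ± 0.0425 (133 ± 4.34 CPM against 95.3 ± 0.876; adjusted p = 2.89e-10) and TIPARP by 0.33 ± 0.0522 (adjusted p = 0.000144), while AHRR did not pass (0.32). The pseudogene PKD1P1, whose counts are uncertain because its parent gene is almost identical (0.72), the Notch target HES4 (0.72) and the flow-responsive transcription factor KLF2 (0.66 ± 0.128; chromosome 19, 16324817 to 16327874) rose next. The readthrough transcript ATP6V1G2-DDX39B, whose reads overlap both parent genes (-0.68), the transcription factor EBF1 (-0.56), NR4A3 (-0.55 ± 0.0704; adjusted p = 3.22e-06) and the growth factor BMP6 (-0.49 ± 0.0882; chromosome 6, 7726797 to 7881422) fell most among the ranked genes. In all, 159 genes rose and 111 fell (247 and 304 without a filter), with 6 and 2 at least 2-fold. The filter of DESeq2 on mean counts left CYP1A1 and EBF1 without an adjusted p, at log2 fold changes of 1.19 (unadjusted p = 8.03e-08) and -0.56 (unadjusted p = 1.00e-05). HES4 lost its call without vehicle replicate 1 (adjusted p = 0.163), 500 replicate 2 (0.0663) or 500 replicate 3 (0.062), and PKD1P1 in all 6 leave-one-out fits (0.0643 to 0.138). The count of 270 became 117 to 161 when any 1 of the 6 libraries was left out and 1679 with only the libraries before the step.

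For Saposhnikoviae Radix the AhR targets lay higher (3 of 8 rose, median 0.17, adjusted p = 3.41e-05, 6.37e-04 with an estimated correlation). Of 19 ER chaperones HYOU1 rose (0.16 ± 0.0331; chromosome 11, 119044189 to 119057202), HSPA5 did not pass (0.10), and the list lay higher (median 0.10, adjusted p = 3.23e-05, adjusted p = 0.00929 with an estimated correlation); without a filter HYOU1 gave adjusted p = 0.222. The 24 ribosome biogenesis genes lay lower (median -0.08, adjusted p = 2.64e-04, adjusted p = 0.0434 with an estimated correlation): the polyamine enzyme ODC1 fell (-0.20), though not without vehicle replicate 2 (adjusted p = 0.0758) or 500 replicate 1 (0.0738), and NPM1 (-0.23) did not pass. Mitosis genes (CCNB2 alone of 26 fell, median -0.10, adjusted p = 1.36e-05, adjusted p = 0.113 with an estimated correlation) and DNA replication genes (1 of 26 fell, median -0.06, adjusted p = 1.03e-04, adjusted p = 0.134 with an estimated correlation) lay lower. CCNB2 (-0.16) lost its call in all 6 leave-one-out fits (0.071 to 0.174) and without a filter (0.13). Lower too were the 34 cytosolic ribosomal protein genes, of which 0 passed (median -0.07, adjusted p = 0.00325, 0.557 with an estimated correlation). The 16 fatty acid synthesis and LXR targets (0 passed, 4 rose and 1 fell when adjusted over the list alone; median 0.09, adjusted p = 0.00165, adjusted p = 0.131 with an estimated correlation) lay higher. Of 28 NRF2 targets 2 rose, among them HMOX1 (0.20) (list median 0.05, adjusted p = 0.0223, adjusted p = 0.396 with an estimated correlation). HMOX1 did not pass without vehicle replicate 3 (0.0541) or 500 replicate 1 (0.0585), and the list call was lost in 2 of 6 leave-one-out fits, up to 0.0619 without vehicle replicate 3.

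At 100 of Saposhnikoviae Radix CYP1A1 rose by 0.79 (adjusted p = 0.0311) but gave 0.0533 to 0.275 in 5 of the 6 leave-one-out fits, and 115 genes passed. The lowest dose had 171. Leave-one-out fits gave 30 to 44 and 62 to 114. From 20 to 500, 5 genes rose and 9 fell. CYP1A1 (0.88 ± 0.182; adjusted p = 0.0260), CYP1B1 (0.47 ± 0.0428) and TIPARP (0.34 ± 0.0529) rose, and the BMP-responsive transcription factors ATOH8 (-0.48 ± 0.0867), ID4 (-0.47 ± 0.0877) and ID2 (-0.35 ± 0.0574), NR4A3 (-0.46 ± 0.0722) and BMP6 (-0.42) fell. The count of 14 became 6 without 500 replicate 1, 5 without 20 replicate 2 and 6 without 20 replicate 3. Each of these 3 libraries also ended the call of CYP1A1 (0.547, 0.0841 and 0.238) and of ATOH8 (0.0797, 0.156 and 0.0748). CYP1A1 was also lost without 20 replicate 1 (0.165) and 500 replicate 3 (0.101). ID4 was lost without 500 replicate 1 (0.0797), 20 replicate 1 (0.0612) and 20 replicate 2 (0.0574), and BMP6 in 4 of 6 fits (0.0612 to 0.877). AhR targets lay higher (median 0.21, adjusted p = 6.86e-16, adjusted p = 3.94e-09 with an estimated correlation), as did NRF2 targets (adjusted p = 2.21e-04, adjusted p = 0.164 with an estimated correlation). TGF-beta genes lay lower (adjusted p = 0.00492, 0.0911 with an estimated correlation), though not without 500 replicate 2 (0.103).

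Saengmaek-san at 500 changed the fewest genes: 61 rose and 45 fell, 0 and 3 of them at least 2-fold. Among the ranked genes KLF2 rose most (0.84 ± 0.127; 10.3 ± 1.53 CPM against 5.70 ± 0.623, n = 3; adjusted p = 8.35e-05), then HES4 (0.70) and the nuclear protein gene BANP (0.54). The glutathione-degrading enzyme CHAC1 (-0.54) and the stress-induced SESN2 (-0.44) fell most of these, followed by the selenoprotein genes GPX1 (-0.43 ± 0.0591; adjusted p = 1.55e-05; chromosome 3, 49357171 to 49358600) and SELENOW (-0.43 ± 0.0636; adjusted p = 5.55e-05; chromosome 19, 47778572 to 47784686), then MARCHF4 (-0.43) and BTG2 (-0.41). The junction protein gene AMOTL2 fell with the smallest adjusted p (-0.35 ± 0.0353; 85.7 ± 4.10 CPM against 110 ± 2.85; adjusted p = 1.09e-08). HES4 and CHAC1 each lost their call in 5 of 6 leave-one-out fits (0.0629 to 0.281 and 0.0546 to 0.114) and SESN2 in 4 (0.0682 to 0.177). MARCHF4 and BTG2 passed in none (0.0554 to 0.264 and 0.0793 to 0.22). The count of 106 became 45, 38 and 23 without vehicle replicates 1, 2 and 3, 51 without 500 replicate 2 and 44 without 500 replicate 3, and 381 with only the libraries before the step. With only the 2 groups in the edgeR fit it was 0, with 1283 genes at unadjusted p under 0.05. Replicate 3 puts the step into that spread. DESeq2 on all groups called 161.

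Among the groups, 19 ER chaperones lay higher with Saengmaek-san (0 rose, 3 when adjusted over the list alone; median 0.08, adjusted p = 9.12e-06, adjusted p = 0.0049 with an estimated correlation), with MANF (0.23) and XBP1 (0.21) not passing. Ribosome biogenesis genes lay lower (0 of 24 passed, median -0.06, adjusted p = 3.23e-05, 0.0178 with an estimated correlation), among them DKC1 (-0.17). DNA replication genes lay lower without a passing member (CCNE2 -0.30, MCM6 -0.12; median -0.07, adjusted p = 3.31e-06, 0.0699 with an estimated correlation). Of the ATF4 genes 1 rose and 3 fell (list median -0.03, adjusted p = 0.0233, 0.259 with an estimated correlation). Of the TGF-beta genes 1 rose and CCN1 fell (-0.27; list median -0.04, adjusted p = 0.0388, 0.193 with an estimated correlation). Of 14 PPAR targets CPT2 rose (0.26; list median 0.02, adjusted p = 0.047, 0.13 with an estimated correlation). Ribosomal protein genes had a median of -0.06 (adjusted p = 0.00726, 0.563 with an estimated correlation). Single libraries ended the last 4 list calls, with highest values of 0.0822 without 500 replicate 3, 0.14 and 0.142 without 500 replicate 1, and 0.122 without 500 replicate 2. They also ended those of CCN1 (0.0849 without vehicle replicate 3) and, in 5 of 6 fits, CPT2 (0.0682 to 0.318).

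No gene passed at 500 against 20 of Saengmaek-san in edgeR, where 469 had an unadjusted p under 0.05. DESeq2 called 2 and edgeR without a filter 53. CYP1B1 (0.08), CXCL8 (-0.00) and HMOX1 (0.08) stood near 0. The TGF-beta and mesenchymal genes lay lower as a group (median -0.05, adjusted p = 4.78e-04, adjusted p = 0.0312 with an estimated correlation; 2 fell when adjusted over the list alone). Against vehicle, 115 genes passed at 100 and 78 at 20. Leave-one-out fits gave 23 to 127 and 17 to 67.

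Guibi-tang at 500 raised chemokine and acute phase genes. The neutrophil chemokines CXCL1 (chromosome 4, 73869393 to 73871242) and CXCL8 (chromosome 4, 73740506 to 73743716) rose by 3.01 ± 0.197 (8.05 ± 1.32 CPM against 0.994 ± 0.0939, n = 3; adjusted p = 1.71e-15) and 2.67 ± 0.172 (5.96 ± 0.619 CPM against 0.926 ± 0.240; adjusted p = 1.47e-15), the iron-carrier protein LCN2 by 2.49 ± 0.230 (chromosome 9, 128149071 to 128153455), the adhesion molecule ICAM1 by 1.73 ± 0.299, the complement factor CFB by 1.60 ± 0.207 and CXCL2 by 1.45 ± 0.130. CXCL5, the most abundant of these chemokines (chromosome 4, 73995642 to 73998779), rose by 1.35 ± 0.0476 (136 ± 9.88 CPM against 53.6 ± 1.44; adjusted p = 1.03e-25), and complement C3 (chromosome 19, 6677704 to 6730562) by 0.99 ± 0.0687. The microtubule-associated TPPP3 (-0.83), C1orf116 (-0.71), the tetraspanin-like TM4SF4 (-0.65) and SESN2 (-0.60) fell most among the ranked genes. In total 454 genes rose and 308 fell, 20 and 10 of them at least 2-fold. In DESeq2, the filter on mean counts left 5 of the named genes without an adjusted p, with log2 fold changes of 2.68 for CXCL8, 2.50 for LCN2, 1.74 for ICAM1, 1.61 for CFB and 1.16 for RRAGD and unadjusted p of 4.97e-08 or less. The count of 762 became 421 without vehicle replicate 2, 494 without vehicle replicate 3 and 444 without 500 replicate 2, and was 1880 with only the libraries before the step and 242 with only these 2 groups in the fit.

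Of the 16 NF-kB and inflammatory genes, 12 rose with Guibi-tang at 500 and 0 fell (median 1.09, adjusted p = 1.67e-41, adjusted p = 8.79e-14 with an estimated correlation), among them the NF-kB inhibitors TNFAIP3 (1.11) and NFKBIA (0.46). RELB (0.28), NFKB1 (0.14), NFKB2 (0.16) and TNFAIP2 (0.23) passed only when adjusted over the list alone. Of 24 lysosome and autophagy genes 13 rose, among them the Rag GTPase RRAGD (1.15), the sialidase NEU1 (0.61 ± 0.0595; chromosome 6, 31857659 to 31862906) and the autophagy receptor SQSTM1 (0.52) (list median 0.14, adjusted p = 3.96e-18, adjusted p = 4.51e-05 with an estimated correlation). LAMP1 did not pass (0.02). Of 19 ER chaperones 10 rose, 15 when adjusted over the list alone, among them HSPA5 (0.19) and HYOU1 (0.21) (median 0.14, adjusted p = 5.23e-12, adjusted p = 2.45e-05 with an estimated correlation). Of 12 complement and acute phase genes LCN2, CFB, C3, C1R (0.27) and C1S (0.22) rose (median 0.24, adjusted p = 3.28e-05, adjusted p = 0.0158 with an estimated correlation). DNA replication genes lay lower (4 of 26 fell, 9 when adjusted over the list alone, among them RRM2 (-0.17) and RRM1 (-0.14); median -0.10, adjusted p = 9.95e-09, adjusted p = 0.0269 with an estimated correlation). Ribosome biogenesis genes did too (4 of 24 fell, among them ODC1 (-0.25); median -0.09, adjusted p = 2.11e-05, 0.0158 with an estimated correlation). RRM1 and RRM2 gave adjusted p of 0.242 and 0.0741 without a filter on low counts. Mitosis genes lay lower (3 of 26 fell, among them CDC20 (-0.23); median -0.09, adjusted p = 2.11e-05, 0.122 with an estimated correlation).

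Smaller group shifts with Guibi-tang were those of 17 interferon genes (median 0.07, adjusted p = 0.0233, adjusted p = 0.0499 with an estimated correlation), 14 PPAR targets (PLIN2 rose by 0.35; median 0.07, adjusted p = 0.0238, adjusted p = 0.104 with an estimated correlation), 34 ribosomal protein genes (median -0.08, 0 passed, adjusted p = 2.10e-04, adjusted p = 0.448 with an estimated correlation) and 33 nuclear oxidative phosphorylation genes (median -0.06, 0 passed, adjusted p = 0.00984, adjusted p = 0.626 with an estimated correlation). The interferon call was lost without 500 replicate 2 (0.062), the PPAR call in 2 of 6 leave-one-out fits (up to 0.067 without 500 replicate 1) and the oxidative phosphorylation call without 500 replicate 3 (0.256), the 1 library of the 3 that lies after the step, where the mitochondrial share is higher. With a term for the step the oxidative phosphorylation list gave 0.272.

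CXCL8 rose by 1.48 at 100 (adjusted p = 1.59e-06) and 0.84 at 20 (adjusted p = 0.0179) of Guibi-tang. The call at 20 was lost without vehicle replicate 3 (adjusted p = 0.159), without 20 replicate 2 (0.104) and with only the libraries before the step, which hold 1 library of 20 (0.155). DESeq2 gave 1.49 at 100 without an adjusted p. At 100, 243 genes passed (leave-one-out 75 to 565) and 233 at 20 (72 to 613). Both highs lack replicate 1, the only one before the step. Between the 500 and 20 doses CXCL8 (1.83 ± 0.165), CXCL1 (1.70 ± 0.180), CXCL5 (1.12 ± 0.0476) and CXCL2 (1.03 ± 0.130) rose most, and TPPP3 (-0.69), ID4 (-0.66 ± 0.0912) and CRYAB (-0.64) fell most among the ranked genes. The NF-kB list (10 of 16 rose, median 0.81, adjusted p = 3.10e-35, adjusted p = 4.51e-13 with an estimated correlation) and the lysosome list (10 of 24 rose, median 0.19, adjusted p = 4.23e-29, adjusted p = 3.26e-07 with an estimated correlation) were called again. In total 129 genes rose and 43 fell. Of the 172 calls 128 were also called against vehicle, and the higher genes had a median of 0.02 at 100. Without a filter 184 rose and 232 fell. Leaving out 500 replicate 1 or 2 gave 109 and 94, 20 replicate 1, 2 or 3 gave 259, 91 and 109. Because 2 libraries of 500 and 1 of 20 lie before the step, the fit was repeated inside each part, with 68 genes before it and 27 after it. In each part 1 of the 2 groups is a single library and other groups supply the spread, so a lost call there does not count against a gene. TPPP3 (0.152 and 0.685) and CRYAB (0.187 and 0.853) passed in neither part. CRYAB was also lost without 500 replicate 1 (0.0902), 500 replicate 2 (0.156) or 20 replicate 2 (0.235).

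Other list calls at 500 against 20 of Guibi-tang held only at the preset correlation. The mitosis genes (median -0.08, adjusted p = 2.27e-05, adjusted p = 0.164 with an estimated correlation) and the mitochondrially encoded transcripts (median -0.37, adjusted p = 3.44e-04, adjusted p = 0.681 with an estimated correlation) lay lower. The cholesterol genes (adjusted p = 0.00963, adjusted p = 0.486 with an estimated correlation) and ER chaperones (adjusted p = 0.00963, adjusted p = 0.129 with an estimated correlation) lay higher. The complement list was called higher (adjusted p = 0.0231, adjusted p = 0.211 with an estimated correlation) although its median was -0.04, since its mean was 0.31 with LCN2 and C3 far above the rest. This was the only called list where median, mean and test differed in sign. Single libraries ended 4 of these 5 calls, with highest values of 0.229 for cholesterol without 500 replicate 1, 0.13 for ER chaperones and 0.1 for complement without 500 replicate 3, and 0.0951 for mitochondrially encoded transcripts without 500 replicate 2. A term for the step gave 0.0761 for the last.

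Soyo-san at 500 raised both sets of genes. CXCL1 rose by 3.06 ± 0.196 (8.30 ± 0.903 CPM against 0.994 ± 0.0939, n = 3; adjusted p = 5.27e-16), CXCL8 by 2.78 ± 0.171 (adjusted p = 1.64e-16), LCN2 by 2.03 ± 0.234, ICAM1 by 1.91 ± 0.294, CFB by 1.78 ± 0.203, the cytokine IL32 by 1.56 ± 0.165 and the monocyte chemokine CCL2 by 1.55 ± 0.153 (chromosome 17, 34255218 to 34257203). CXCL5 rose by 1.16 ± 0.0475 (120 ± 4.96 CPM against 53.6 ± 1.44), and the AhR targets CYP1A1 and CYP1B1 rose by 1.53 ± 0.179 (adjusted p = 4.11e-08) and 0.72 ± 0.0425 (157 ± 1.49 CPM against 95.3 ± 0.876; adjusted p = 5.38e-17). The calcium-binding S100P (fold 0.501), ATOH8 (-0.89 ± 0.0891; chromosome 2, 85751344 to 85788066), ID4 (-0.89 ± 0.0920; chromosome 6, 19837386 to 19840684) and the WNT-receptor ubiquitin ligase RNF43 (-0.74) fell. In total 536 genes rose and 505 fell (616 and 665 without a filter), 29 and 12 of them at least 2-fold. For ICAM1, DESeq2 gave a log2 fold change of 1.92 without an adjusted p. The count of 1041 became 650, 574 and 560 without vehicle replicates 1, 2 and 3 and 603 and 651 without 500 replicates 1 and 2. Soyo-san lies after the step and vehicle before it, so no fit inside 1 part was possible. A term for the step gave 2014.

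Of the 16 NF-kB genes 12 rose with Soyo-san at 500 (median 1.08, adjusted p = 9.05e-38, adjusted p = 2.15e-13 with an estimated correlation), and PTGS2 (0.12) and NFKB1 (0.11) did not pass. Of 8 AhR targets 3 rose (median 0.18, adjusted p = 8.57e-06, 1.95e-04 with an estimated correlation) and AHRR did not pass (0.34). Of 12 complement genes 5 rose, among them LCN2, CFB and C3 (0.96) (median 0.23, adjusted p = 7.22e-06, 0.00744 with an estimated correlation). ER chaperones lay higher (4 of 19 rose, among them HYOU1 (0.17); median 0.09, adjusted p = 0.00111, 0.0438 with an estimated correlation). Interferon genes did too (2 of 17 rose, 1 fell, and IFIT1 did not pass (0.13); median 0.20, adjusted p = 0.0233, adjusted p = 0.0499 with an estimated correlation). Ribosome biogenesis genes lay lower (2 of 24 fell, median -0.07, adjusted p = 5.34e-04, 0.0499 with an estimated correlation). Without a filter HYOU1 gave adjusted p = 0.0881.

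Held only at the preset correlation were the falls of 18 heat shock genes (DNAJB1 -0.22, 4 fell; median -0.11, adjusted p = 2.54e-04, adjusted p = 0.266 with an estimated correlation) and DNA replication genes (4 of 26 fell, median -0.10, adjusted p = 1.61e-05, adjusted p = 0.106 with an estimated correlation). The same held for the rise of 22 TGF-beta genes (BHLHE40 0.37; median 0.06, adjusted p = 0.0211, 0.14 with an estimated correlation). Ribosomal protein genes had a median of -0.06 (adjusted p = 0.0203, adjusted p = 0.61 with an estimated correlation), lost in 3 of 6 leave-one-out fits (up to 0.0847 without 500 replicate 1). The groups that move with the mitochondrial share were higher for 13 mitochondrially encoded transcripts (median 0.51, 0 passed, adjusted p = 0.00225, adjusted p = 0.563 with an estimated correlation) and lower for 33 nuclear oxidative phosphorylation genes (median -0.14, 2 fell, adjusted p = 6.72e-05, adjusted p = 0.486 with an estimated correlation). The first was lost without 500 replicate 1 (0.15). A term for the step, which likely removes too much here, turned it lower (adjusted p = 0.00502) and ended the second (0.87). It also ended the calls of SERPINA3 (0.0881), CALR (0.878) and MCM6 (0.613).

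At 100 of Soyo-san CXCL8 rose by 1.35 (adjusted p = 1.72e-05; 1.35 without an adjusted p in DESeq2) and at 20 it did not pass (0.49; adjusted p = 0.203). The counts were 306 at 100, with 106 to 181 in leave-one-out fits, and 344 at 20, with 78 to 388. From the lowest to the highest dose, 57 genes rose and 49 fell. CXCL8 (2.29 ± 0.171), CXCL1 (2.01 ± 0.184), CYP1A1 (1.25 ± 0.183), CCL2 (1.23 ± 0.154) and IL32 (1.15 ± 0.166) rose most among the ranked genes. ID4 (-0.89 ± 0.0945), ATOH8 (-0.69 ± 0.0926), NR4A2 (-0.61) and NR4A3 (-0.58 ± 0.0725) fell most of these. NR4A2 lost its call in 5 of 6 leave-one-out fits (0.0637 to 0.349). Of the 106 calls 84 were also called against vehicle, and the higher genes had a median of 0.20 at 100. Without a filter 89 rose and 88 fell. NF-kB genes (11 of 16 rose, median 0.85, adjusted p = 3.98e-51, adjusted p = 3.14e-15 with an estimated correlation), AhR targets (3 of 8, median 0.29, adjusted p = 6.43e-15, adjusted p = 7.81e-09 with an estimated correlation), complement genes (4 of 12, median 0.24, adjusted p = 6.61e-06, adjusted p = 0.00898 with an estimated correlation) and interferon genes (adjusted p = 0.00526, adjusted p = 0.0134 with an estimated correlation) were higher. ATF4 genes (adjusted p = 0.00465, adjusted p = 0.164 with an estimated correlation) and ER chaperones (adjusted p = 0.0364, adjusted p = 0.211 with an estimated correlation) were higher only at the preset correlation. Ribosome biogenesis genes were lower (adjusted p = 0.0478, 0.327 with an estimated correlation). The last 2 lists passed in only 2 of 6 leave-one-out fits (up to 0.0892 without 20 replicate 1 and 0.208 without 500 replicate 1). The count of 106 became 63 and 69 without 20 replicates 1 and 3 and 62 and 67 without 500 replicates 2 and 3.

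Okbyeongpung-san at 500 raised the chemokine genes without a CYP1A1 call (0.53; adjusted p = 0.137). CXCL1 rose by 2.53 ± 0.201 (5.77 ± 0.444 CPM against 0.994 ± 0.0939, n = 3; adjusted p = 1.62e-12), CXCL8 by 2.37 ± 0.175 (adjusted p = 1.87e-13), LCN2 by 1.48 ± 0.244, ICAM1 by 1.37 ± 0.306, IL32 by 1.32 ± 0.168 (chromosome 16, 3065297 to 3082192), CFB by 1.28 ± 0.210 and CXCL2 by 1.10 ± 0.133. CXCL5 rose by 0.93 ± 0.0476 (102 ± 2.42 CPM against 53.6 ± 1.44; adjusted p = 3.35e-19) and CYP1B1 by 0.20 ± 0.0428. The antiproliferative BTG2 (-0.60), the stretch-responsive ANKRD1 (-0.55) and SESN2 (-0.55) fell, after UBAP1L (-0.67), which lost its call with a term for the step (0.0938). In total 338 genes rose and 247 fell, 13 and 7 of them at least 2-fold. DESeq2 gave log2 fold changes of 1.38 for ICAM1, 1.48 for LCN2 and 1.29 for CFB without an adjusted p, and ICAM1 was lost without 500 replicate 1 (0.0551). The count of 585 became 272 to 340 when any 1 of the 6 libraries was left out. Vehicle and this extract lie on opposite sides of the step, and a term for it gave 2154.

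Of 16 NF-kB genes 12 rose with Okbyeongpung-san at 500 (median 0.92, adjusted p = 2.53e-33, adjusted p = 1.06e-12 with an estimated correlation), with PTGS2 (0.14) and RELB (0.24) not passing. Of 19 ER chaperones 5 rose, among them HYOU1 (0.25) and HSPA5 (0.13) (median 0.13, adjusted p = 1.05e-06, 0.00166 with an estimated correlation). Of 12 complement genes LCN2, CFB and C3 (0.79) rose and the fibrinogens did not pass (FGB -0.01; median 0.09, adjusted p = 0.00141, adjusted p = 0.0668 with an estimated correlation). Of 24 cholesterol synthesis genes 4 fell, among them HMGCS1 (-0.19 ± 0.0445) (median -0.10, adjusted p = 1.36e-05, 0.127 with an estimated correlation). A term for the step ended the calls of the list (0.809) and HMGCS1 (0.239). HMGCS1 was also lost without 500 replicate 1 (0.0836). Of 22 TGF-beta genes 4 rose, among them BHLHE40 (0.42) and LTBP2 (0.26), and CCN1 (-0.45) and CCN2 (-0.26) fell (median 0.11, adjusted p = 0.00636, adjusted p = 0.0974 with an estimated correlation; 0.108 with a term for the step). Lower at the preset correlation were DNA replication genes (3 of 26 fell, median -0.07, adjusted p = 2.11e-05, adjusted p = 0.11 with an estimated correlation), ribosome biogenesis genes (3 of 24 fell, median -0.03, adjusted p = 0.00435, adjusted p = 0.11 with an estimated correlation), ribosomal protein genes (median -0.05, adjusted p = 0.00322, adjusted p = 0.557 with an estimated correlation), heat shock genes (median -0.07, adjusted p = 0.0185, adjusted p = 0.543 with an estimated correlation) and nuclear oxidative phosphorylation genes (median -0.12, 0 passed, adjusted p = 7.37e-06, adjusted p = 0.385 with an estimated correlation). The heat shock call was lost without 500 replicate 3 (0.0551), and a term for the step ended those of DNA replication (0.138) and oxidative phosphorylation (0.94).

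At 100 of Okbyeongpung-san CXCL8 rose by 1.20 (adjusted p = 0.000222; 1.20 without an adjusted p in DESeq2), and at 20 it did not pass (0.70; adjusted p = 0.0748). The counts were 237 at 100, with 70 to 303 in leave-one-out fits, and 188 at 20, with 70 to 117. From 20 to 500 of this decoction 17 genes rose and 0 fell, the ranked ones led by CXCL1 (1.82 ± 0.198), CXCL8 (1.67 ± 0.173), CCL2 (0.91 ± 0.163) and IL32 (0.83 ± 0.169). IL32 was lost in 5 of 6 leave-one-out fits (0.0581 to 0.234) and CCL2 without 20 replicate 1 (0.0775). Of these calls 16 were also called against vehicle, and the genes had a median of 0.37 at 100. Without a filter 45 rose and 48 fell. The count of 17 became 11 and 10 without 20 replicates 1 and 2 and 11 without 500 replicate 3. NF-kB genes (8 of 16 rose, median 0.74, adjusted p = 4.39e-49, adjusted p = 3.35e-15 with an estimated correlation), complement genes (2 of 12 rose, median 0.08, adjusted p = 7.88e-05, adjusted p = 0.0223 with an estimated correlation) and ER chaperones (0 rose, 3 when adjusted over the list alone, adjusted p = 2.53e-04, adjusted p = 0.0223 with an estimated correlation) were higher. Cholesterol genes were lower (adjusted p = 2.21e-04, adjusted p = 0.271 with an estimated correlation), and TGF-beta (adjusted p = 0.0344, adjusted p = 0.211 with an estimated correlation) and heat shock genes (adjusted p = 0.0389, adjusted p = 0.697 with an estimated correlation) higher. The latter 2 lists passed in only 2 of 6 leave-one-out fits (up to 0.225 and 0.459 without 20 replicate 3).

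**Figure D2:**
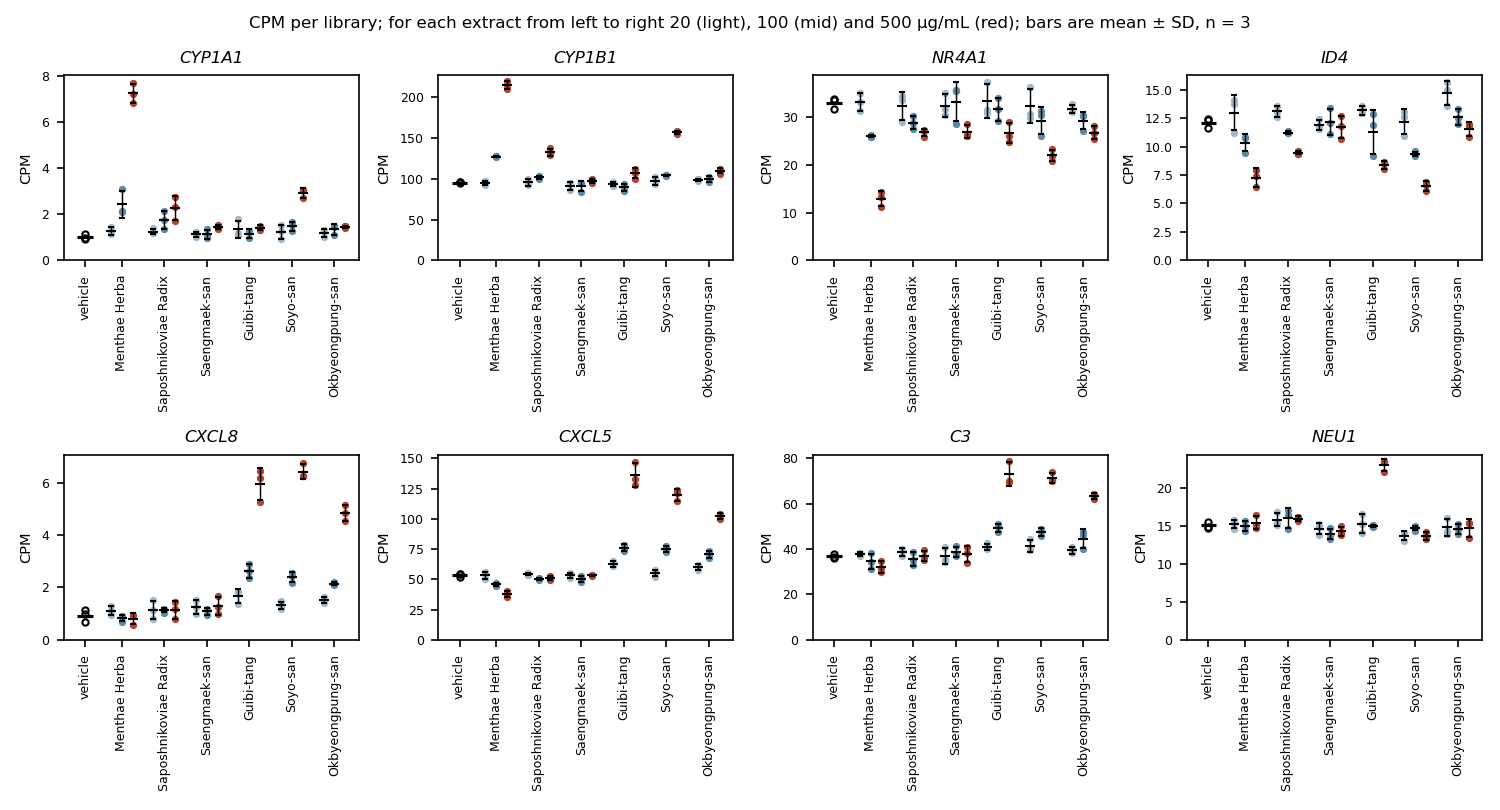
CPM of 8 named genes in each library by extract and dose. Points are single libraries.

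**Figure D3:**
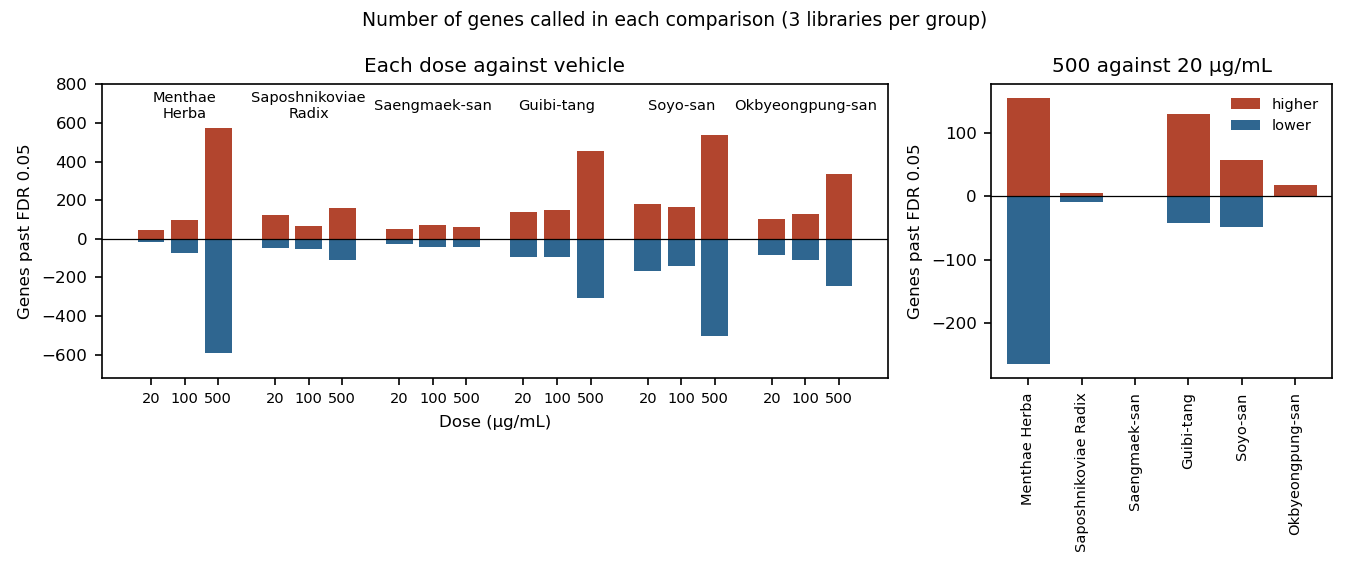
Genes past FDR 0.05 against vehicle by extract and dose, higher and lower. Counts come from the fit of 57 libraries.

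Over all extracts at 500 against vehicle, 56 of 174 list tests were called, 27 higher and 29 lower. With an estimated correlation 22 remained, and fry called 54, 42 of them among the 56. Leave-one-out fits gave 51 to 59. The other 8 groups were called in no extract, against vehicle or against 20. The smallest adjusted p among them at 500 against vehicle was 0.0633 for 22 p53 targets (Menthae Herba, median 0.06, with CDKN1A at -0.13), 0.377 for 6 metallothioneins (Okbyeongpung-san, median -0.05), 0.675 for 5 PXR and CAR targets (Soyo-san, median 0.10), 0.0744 for 17 glucocorticoid receptor targets (Saengmaek-san, median 0.05), 0.224 for 16 immediate early genes (Saengmaek-san, median -0.04), 0.343 for 15 circadian clock genes (Saposhnikoviae Radix, median -0.05), 0.129 for 9 replication-dependent histones (Saposhnikoviae Radix, median -0.14) and 0.199 for 5 fibroblast markers (Saposhnikoviae Radix, median 0.17). Only 3 leukocyte and 1 endothelial markers passed the count filter, too few to test. The proliferation marker MKI67 passed in no extract at 500 in the fixed panel (-0.17 with Menthae Herba, 0.05 with Soyo-san).

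**Figure D4:**
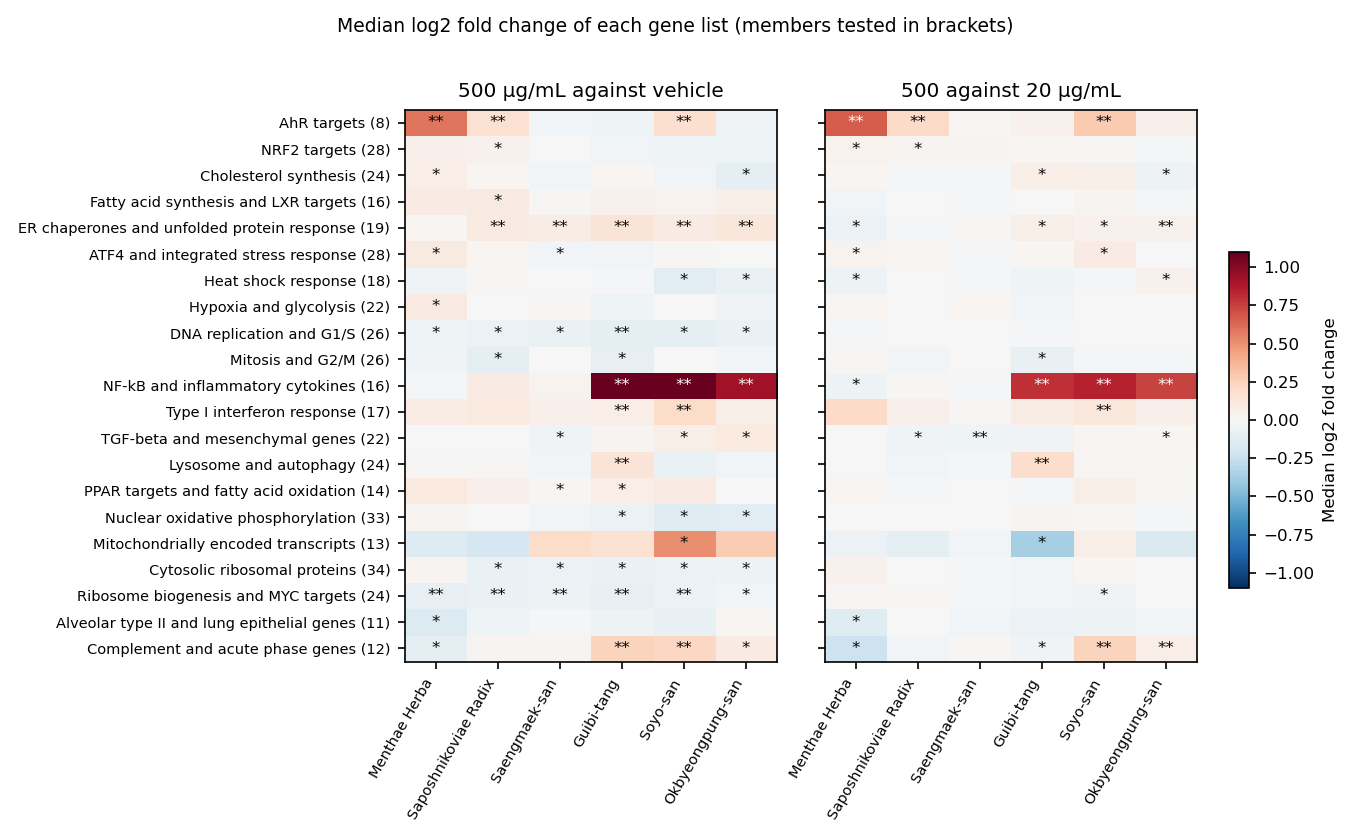
Median log2 fold change of each list at 500 against vehicle and against 20. An asterisk marks lists called with the preset correlation and 2 asterisks those also called with an estimated correlation.

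Soyo-san contains Menthae Herba at a share the labels do not give, so comparing both at 500 does not match herb doses. CXCL1 (3.16 ± 0.208), CXCL8 (3.01 ± 0.185), CXCL5 (1.67 ± 0.0496) and CCL2 (1.53 ± 0.158) were higher with Soyo-san, and CYP1A1 (-1.30 ± 0.150) was higher with the herb. The antisense transcript TUBA1B-AS1 had the largest difference (7.45), which is uncertain because it overlaps an abundant tubulin gene. For it 5 of 6 leave-one-out fits lost the call (0.0524 to 0.148) and a term for the step ended it (0.719). The difference of TMEM160 (-1.21) vanished with that term (0.03, adjusted p = 0.987), as did those of FMC1 (0.835), SNHG19 (0.901) and DHRS13 (0.287). These 4 also lost their calls without Soyo-san replicate 1 (0.213, 0.144, 0.167 and 0.102). Each Menthae Herba replicate and Soyo-san replicate 2 ended that of TMEM160 (0.0618 to 0.123), and Menthae Herba replicates 1 and 3 those of FMC1 (0.0776 and 0.0517) and SNHG19 (0.0734 and 0.051). DESeq2 gave CXCL1 (3.17), CXCL8 (3.01) and CYP1A1 (-1.31) no adjusted p. In total 542 genes were higher and 517 lower. The count of 1059 became 402, 579 and 547 without Menthae Herba replicates 1, 2 and 3 and 314 without Soyo-san replicate 1, and a term for the step gave 489. For 51 genes (88 with a term for the step) the 500-against-20 change itself differed, with 45 higher for Soyo-san, led by CXCL5 (difference 1.62), NPTX1 (0.54) and C3 (1.03), and 6 lower, led by TIPARP (-0.77) and CYP1B1 (-0.49). At 20, 369 genes already differed; the 2 extracts lie on opposite sides of the step.

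Okbyeongpung-san contains Saposhnikoviae Radix, also at an unstated share. At 500, CXCL1 (2.42 ± 0.205), IL32 (1.22 ± 0.170), CCL2 (1.10 ± 0.161), CXCL5 (1.01 ± 0.0482) and CXCL2 (0.98 ± 0.135) were higher with the decoction, and MVP-DT (-0.76), FCGBP (-0.73), RPSAP58 (-0.65), AP1M2 (-0.59) and ACAD8 (-0.54) lower. All 5 lower genes lost their calls with a term for the step (0.524 to 0.742), and each in 4 or more leave-one-out fits (0.0512 to 0.224). In total 98 genes were higher and 71 lower. Any 1 library left out gave 49 to 67 of the 169. The 500-against-20 change differed for 8 genes (15 with a term for the step), among them CXCL5 (difference 0.86), C3 (0.75), CXCL8 (1.72) and CXCL1 (1.94) higher for the decoction and CYP1B1 (-0.32) lower. At 20, 10 genes differed.

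Between the 2 herbs at 500, CYP1A1 (1.65 ± 0.153), TIPARP (0.96 ± 0.0510), AHRR (0.79 ± 0.116), CYP1B1 (0.70 ± 0.0422) and GACAT2 (0.66) were higher with Menthae Herba, and NR4A1 (-1.05 ± 0.0933), SDS (-0.75), H19 (-0.74), TPPP3 (-0.73) and RNF43 (-0.72) lower. In total 85 genes were higher and 169 lower. The count of 254 became 164 and 143 without Menthae Herba replicates 2 and 3 and 160 and 148 without Saposhnikoviae Radix replicates 2 and 3, and 623 with only the libraries before the step. Dose changes differed for 34 genes (69 with a term for the step), among them TIPARP (0.98), CYP1B1 (0.70) and NR4A1 (-1.09). At 20, edgeR called 0 genes between the herbs.

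Saengmaek-san had lower CXCL1 (-2.67 ± 0.196), CXCL8 (-2.24 ± 0.170), CXCL2 (-1.51 ± 0.135), CXCL5 (-1.35 ± 0.0480) and IL32 (-1.19 ± 0.171) than Guibi-tang at 500, and higher TPPP3 (0.67), C1orf116 (0.62), the keratin KRT4 (0.52), TM4SF4 (0.51) and ID4 (0.48). The fit of the libraries after the step holds 1 library of each extract at 500, with the spread taken from other groups. The 5 higher genes did not pass there (0.0831 to 0.95), which does not count against them. In total 37 genes were higher and 136 lower. The count of 173 became 115 and 103 without Saengmaek-san replicates 2 and 3, 109 and 106 without Guibi-tang replicates 1 and 2, and 29 after the step alone. Dose changes differed for 51 genes (77 with a term for the step), among them CXCL5 (-1.11), SQSTM1 (-0.59), LCN2 (-3.04) and NEU1 (-0.61). At 20, edgeR called 0 genes between them.

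Soyo-san and Okbyeongpung-san differed least. TIPARP (0.53 ± 0.0529) and CYP1B1 (0.52 ± 0.0426) were higher with Soyo-san, and ID4 (-0.82 ± 0.0948), ATOH8 (-0.68 ± 0.0925), GPX1 (-0.54 ± 0.0606), IGFBP5 (-0.46) and ID2 (-0.41 ± 0.0579) lower. CXCL5 was higher by 0.23 ± 0.0465 in the fit of all groups, a call lost in 5 of 6 leave-one-out fits (0.0523 to 0.244) and in the fit of libraries after the step (0.0608). In total 8 genes were higher and 15 lower (65 and 51 without a filter). Any 1 library left out gave 11 to 15 of the 23, and the fit after the step gave 12. Dose changes differed for 5 genes (6 with a term for the step): CYP1B1 (0.54), TIPARP (0.52), GPX1 (-0.47), CXCL5 (0.35) and GRAMD1B (-0.28). At 20, edgeR called 0 genes between them.

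Dose responses were shared in part. Between Guibi-tang and Soyo-san 29 genes rose in both at 500 against 20, where 0.426 would be shared at random, and 12 fell in both (0.122). Guibi-tang and Okbyeongpung-san shared 15 higher genes (0.127), Soyo-san and Okbyeongpung-san 15 (0.0562), and Menthae Herba and Soyo-san 16 higher (0.512) and 37 lower (0.752). Menthae Herba and Saposhnikoviae Radix shared 5 higher (0.0449) and 9 lower (0.138), which are all 14 calls of the second, and Menthae Herba and Guibi-tang 5 higher (1.16) and 22 lower (0.660). Saposhnikoviae Radix shared 1 higher (0.0374) and 4 lower (0.0224) with Guibi-tang and 4 higher (0.0165) and 6 lower (0.0256) with Soyo-san. The other 7 pairs shared 0. Across all 17256 genes the median correlation of the 15 pairs of extracts was 0.0279 (-0.0322 to 0.111; median rho 0.0769), and 0.161 over 10937 genes of 5 CPM or more, where it reached 0.359 for Menthae Herba and Soyo-san and 0.278 for Guibi-tang and Soyo-san. Removing the step gave 0.0356, beside 0.0433 for plain log2 CPM differences. Against vehicle the median was 0.445, while simulated unchanged groups sharing 3 control libraries gave 0.462 (0.378 to 0.532). The covariance was 0.0617 against 0.0420 in the simulation, a difference of 0.0198. The simulation held shared controls but no step in the library order. The correlation was 0.556 for the 2 herbs and 0.587 for Soyo-san and Okbyeongpung-san, pairs on 1 side of it, and 0.282 to 0.322 for herbs with these 2 decoctions. The 3 vehicle libraries are too few to divide, so part of the excess can come from vehicle standing apart or the step.

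Soshiho-tang was described without a test, from 1 library per dose. At 500, TSC22D3, a glucocorticoid-induced leucine zipper gene, stood at a log2 ratio to the vehicle mean of 1.41 (20.8 CPM against 7.49 ± 0.237), ALDH1L2, a mitochondrial folate enzyme, at 1.31, CBS at 1.05, CXCL5 at 1.03, KIF21B at 1.00 and TIPARP at 1.00. The inducible chaperones HSPA1A (-0.89) and HSPA1B (-0.76), the selenoprotein SELENOW (-0.83) and DNAJB4 (-0.75) stood lowest. Of the panel, TRIB3 stood at 1.66, DDIT3 at 1.26, CYP1A1 at 1.56, CYP1B1 at 0.92, CXCL8 at 1.94 and HMOX1 at 0.81; at 100 and 20 TRIB3 was 0.02 and 0.04, DDIT3 -0.11 and -0.25, HMOX1 -0.03 and 0.04 and CXCL8 -0.17 and 0.48. CYP1A1 stood at 0.71 and 1.13, CYP1B1 at 0.45 and 0.65 and TIPARP at 0.32 and 0.44, higher at 20 than at 100. The medians of ATF4 genes (0.55), NF-kB genes (0.52), AhR targets (0.50), fatty acid and LXR genes (0.36), cholesterol genes (0.34), ER chaperones (0.27), immediate early genes (0.27) and mitochondrially encoded transcripts (0.25) exceeded all 10000 matched random lists, and those of heat shock (-0.42), DNA replication (-0.24), mitosis (-0.22) and nuclear oxidative phosphorylation genes (-0.18) lay under all. At 100 and 20 the mitochondrially encoded transcripts had medians of 0.32 and 0.28. All 3 libraries lie after the step, vehicle before it, and 1550 genes stood higher and 2221 lower at both 500 and 100 outside the vehicle range, so differences of the size of the step cannot be told from the extract.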

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

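The libraries after the 31st in library order stood apart from the rest. A term for this step called 7534 genes, 3709 higher and 3825 lower, with a median size of 0.19 log2. Against a few genes taking most of the counts, 7528 remained after the mitochondrially encoded genes were removed, and against depth, 6924 remained when every library was thinned to the lowest total; rho across genes was -0.000599 with GC content and -0.0877 with transcript length. The 18 Saengmaek-san and Guibi-tang libraries alone gave 7330. Only their groups span the step, so 7534 rests on them too. They also helped place the step, so 7330 cannot tell whether it is a library batch. Open is what changed at the step, since the labels hold no dates of culture, library or run.

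Many genes were called at 20 against vehicle. The calls of the 6 extracts summed to 1080, and 125 genes were called in 3 or more extracts in the same direction, in comparisons that share the 3 vehicle libraries. The signed change of the called genes at 20 had medians of 0.25 to 0.27, yet from 100 to 500 it moved by -0.00 to 0.02 in the 6 extracts, with a median over extracts of 0.0131. That is consistent with vehicle libraries standing apart. Against depth, the sum was 1082 with the vehicle libraries thinned to the median total. Open is whether vehicle stood apart by its place in the library order, by DMSO, which only its labels name, or by the extracts at 20.

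The chemokine genes CXCL1, CXCL8 and CXCL5 rose with Guibi-tang, Soyo-san and Okbyeongpung-san. Against the step in the library order, all libraries of Soyo-san and Okbyeongpung-san lie after it, and at least 8 of the 16 NF-kB genes rose in each at 500 against 20. Against cells of another type, the summed leukocyte markers gained 0.663% of what the NF-kB genes gained, with PTPRC at 0 CPM and CD74 at 0.262 CPM in vehicle. Endotoxin in the extracts, on which the sources used here give nothing, stays open as a possible explanation.

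The dose change differed from that of a comparison extract for 51 genes with Soyo-san against Menthae Herba, with the smallest adjusted p for CXCL5. It differed for 8 genes with Okbyeongpung-san against Saposhnikoviae Radix, 34 with Menthae Herba against Saposhnikoviae Radix, 51 with Saengmaek-san against Guibi-tang and 5 with Soyo-san against Okbyeongpung-san, each listed because its 2 extracts were tested against each other and differed.

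The 6 libraries of a comparison can be divided in only 10 ways, too few for a share under 0.05. In fits of 2 groups, the genes called in the real division, with the highest other division in brackets, were at 500, 100 and 20 against vehicle 3023 (2), 1133 (2) and 943 (1) for Menthae Herba, 2217 (1), 763 (3) and 1202 (1) for Saposhnikoviae Radix, 0 (2), 2 (1) and 0 (4) for Saengmaek-san. The same values were 242 (1), 16 (2) and 9 (1) for Guibi-tang, 2132 (1), 424 (2) and 1019 (2) for Soyo-san, 2854 (2), 219 (3) and 934 (4) for Okbyeongpung-san. For 500 against 20 they were 887 (1) for Menthae Herba, 35 (7) for Saposhnikoviae Radix, 0 (0) for Saengmaek-san, 14 (3369) for Guibi-tang, 34 (38) for Soyo-san, 16 (3) for Okbyeongpung-san. Between extracts at 500 they were 2822 (1) for Soyo-san against Menthae Herba, 3515 (0) for Okbyeongpung-san against Saposhnikoviae Radix, 724 (2) for Menthae Herba against Saposhnikoviae Radix, 23 (2) for Saengmaek-san against Guibi-tang, 22 (3) for Soyo-san against Okbyeongpung-san. The real division alone had as many calls, 1 of 10, in 24 comparisons. For Soyo-san and Okbyeongpung-san against vehicle or a herb it is also the library-order step, so the 2 cannot be told apart. The number was 2 of 10 for Soyo-san and Guibi-tang 500 against 20 and 10 of 10 where Saengmaek-san had 0 genes. The Guibi-tang division with 3369 follows the step.

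Tests of GC content, transcript length, library batch, the chemokine genes against the step and divisions of libraries were chosen after the results were seen. Those of removed genes, depth, vehicle standing apart, cells of another type and BMP targets were written after the patterns but before their values.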

How the results depend on the processing

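The results differ in how firmly they stand. The rises of CYP1A1, CYP1B1 and TIPARP with Menthae Herba, and of CXCL1 and CXCL5 with Guibi-tang, Soyo-san and Okbyeongpung-san at 500, kept direction and call in every fit of 57 libraries, while most counts of genes moved. The named genes had 555 values, 310 of them called. RLE scaling kept all 310, DESeq2 290 (its filter on mean counts left the other 20 without an adjusted p), the replicate block 309, no filter 274, a term for the step in the library order 275 and the fits of 2 groups 256; leave-one-out fits kept 1500 of 1860. The only change of sign was TMEM160 in Soyo-san against Menthae Herba, at 0.028 with the term for the step. RLE and DESeq2 moved the median of all genes by at most 0.00353 log2 and the share of higher calls by at most 8.14 percentage points. With 3 libraries per group and 18330592 to 35308791 counts per library, changes under 1.5-fold are often missed. Where a count moved, the cause was not tested. The term for the step, fits inside each part and 3 of 5 dose-change tests were chosen after the data were seen.

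With the term for the step, counts against vehicle at 500, 100 and 20 were 2099, 583 and 297 for Menthae Herba, 1001, 354 and 558 for Saposhnikoviae Radix, 376, 178 and 169 for Saengmaek-san, 1725, 446 and 365 for Guibi-tang, 2014, 1239 and 787 for Soyo-san, and 2154, 1216 and 1644 for Okbyeongpung-san. For 500 against 20 they were 715 for Menthae Herba, 27 for Saposhnikoviae Radix and 184 for Soyo-san. Between extracts they were 489 for Soyo-san and Menthae Herba, 439 for Menthae Herba and Saposhnikoviae Radix, 267 for Saengmaek-san and Guibi-tang and 51 for Soyo-san and Okbyeongpung-san. All libraries of Soyo-san and Okbyeongpung-san lie after the step, so for them this term rests on Saengmaek-san and Guibi-tang. Where their own shift is smaller, the term removes too much.

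With only the libraries before the step, counts against vehicle were 2723, 1090 and 741 for Menthae Herba, 1679, 651 and 1068 for Saposhnikoviae Radix, 381, 206 and 194 for Saengmaek-san and 1880, 134 and 105 for Guibi-tang. At 500 against 20 they were 899 for Menthae Herba, 31 for Saposhnikoviae Radix and 68 for Guibi-tang, and 623 for Menthae Herba against Saposhnikoviae Radix. With only the libraries after it they were 27 for Guibi-tang 500 against 20, 29 for Saengmaek-san against Guibi-tang and 12 for Soyo-san against Okbyeongpung-san. Guibi-tang has 1 library each at 100 and 20 before the step and 1 at 500 after it, and Saengmaek-san has 1 at each dose after it, so in these fits other groups supply the spread.

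With only the 2 groups in the edgeR fit, counts against vehicle were 3023, 1133 and 943 for Menthae Herba, 2217, 763 and 1202 for Saposhnikoviae Radix, 0, 2 and 0 for Saengmaek-san, 242, 16 and 9 for Guibi-tang, 2132 at 500 and 1019 at 20 for Soyo-san, and 2854 and 934 for Okbyeongpung-san. For Saengmaek-san at 500 and 20, 1283 and 1383 genes had an unadjusted p under 0.05. Saengmaek-san and Guibi-tang groups span the step, so their low counts do not decide. Counts at 500 against 20 were 887 for Menthae Herba, 35 for Saposhnikoviae Radix, 14 for Guibi-tang and 34 for Soyo-san. Between extracts they were 2822 for Soyo-san and Menthae Herba, 3515 for Okbyeongpung-san and Saposhnikoviae Radix, 724 for Menthae Herba and Saposhnikoviae Radix and 23 for Saengmaek-san and Guibi-tang.

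Without a filter on low counts, counts against vehicle at 100 and 20 were 364 and 256 for Menthae Herba, 725 and 622 for Guibi-tang, 733 and 1081 for Soyo-san and 757 and 533 for Okbyeongpung-san, and at 500, 100 and 20 they were 551, 255 and 307 for Saposhnikoviae Radix and 187, 306 and 214 for Saengmaek-san. For 500 against 20 they were 101 for Saposhnikoviae Radix, 53 for Saengmaek-san, 416 for Guibi-tang, 177 for Soyo-san and 93 for Okbyeongpung-san. Between extracts they were 2057 for Soyo-san and Menthae Herba, 1389 for Okbyeongpung-san and Saposhnikoviae Radix and 116 for Soyo-san and Okbyeongpung-san. Where more genes had risen than fallen, this fit gave more falls for Guibi-tang at 500 against 20 (184 higher, 232 lower), Okbyeongpung-san at 500 against 20 (45 and 48), Saposhnikoviae Radix at 500 (247 and 304) and 100 (116 and 139), Menthae Herba at 100 (143 and 221) and 20 (119 and 137), Soyo-san at 500, 100 and 20 (616 and 665, 355 and 378, 504 and 577) and Okbyeongpung-san at 100 and 20 (344 and 413, 256 and 277). For Soyo-san against Okbyeongpung-san, with more lower genes before, it gave 65 higher and 51 lower. DESeq2 called 136 genes at 20 of Menthae Herba, 272 of Saposhnikoviae Radix, 374 of Guibi-tang, 531 of Soyo-san and 296 of Okbyeongpung-san, and 161, 183 and 118 for Saengmaek-san at 500, 100 and 20. It called 22 for Saposhnikoviae Radix and 2 for Saengmaek-san at 500 against 20, and 321 for Okbyeongpung-san against Saposhnikoviae Radix.

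With 1 library left out in turn, the lowest and highest counts against vehicle at 500, 100 and 20 were 647 and 799, 50 and 95, 16 and 44 for Menthae Herba, 117 and 161, 30 and 44, 62 and 114 for Saposhnikoviae Radix, 23 and 89, 23 and 127, 17 and 67 for Saengmaek-san, 421 and 619, 75 and 565, 72 and 613 for Guibi-tang, 560 and 716, 106 and 181, 78 and 388 for Soyo-san, and 272 and 340, 70 and 303, 70 and 117 for Okbyeongpung-san. The 500-against-20 ranges were 5 and 12 for Saposhnikoviae Radix, 91 and 259 for Guibi-tang, 62 and 78 for Soyo-san and 10 and 14 for Okbyeongpung-san. Between extracts they were 314 and 757 for Soyo-san and Menthae Herba, 49 and 67 for Okbyeongpung-san and Saposhnikoviae Radix, 143 and 184 for Menthae Herba and Saposhnikoviae Radix, 103 and 147 for Saengmaek-san and Guibi-tang, and 11 and 15 for Soyo-san and Okbyeongpung-san. The median similarity of extracts lay between 0.0146 and 0.0440.

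Tests of the dose change itself gave 51 genes for Soyo-san and Menthae Herba, 8 for Okbyeongpung-san and Saposhnikoviae Radix, 34 for Menthae Herba and Saposhnikoviae Radix, 51 for Saengmaek-san and Guibi-tang and 5 for Soyo-san and Okbyeongpung-san. With the term for the step these became 88, 15, 69, 77 and 6. Of the gene lists, 22 were called with an estimated correlation and 32 at 500 against 20. The similarity was 0.161 over genes of 5 CPM or more and 0.445 against vehicle.

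The labels number the libraries of each group 1 to 3, but equal numbers did not pair overall: after removal of group means, libraries of the same number correlated at -0.195 to 0.352 with a median of -0.00439, and in 1 of 29 comparisons all 3 pairs exceeded 0.1. That was Saengmaek-san 500 against 20 (0.117, 0.194 and 0.345), where replicate 3 of each dose lies after the step and the others before it, and the replicate block called 0 genes there. The replicate number as a block gave 1209 genes for Menthae Herba 500 against vehicle, ended the call of CYFIP2 in Soyo-san against Okbyeongpung-san (adjusted p = 0.0547 in edgeR) and changed no other call of a named gene.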

Other observations

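ID2, ID3 and ID4 fell at 500 against 20 in 4 of the 6 extracts. ID4 fell with Menthae Herba (-0.83), Saposhnikoviae Radix (-0.47), Guibi-tang (-0.66) and Soyo-san (-0.89), ID2 by -0.54, -0.35, -0.42 and -0.49 in the same order, and ID3 by -0.51, -0.32, -0.26 and -0.39. These genes encode inhibitors of DNA-binding transcription factors. ATOH8 fell with Menthae Herba (-0.41), Saposhnikoviae Radix (-0.48) and Soyo-san (-0.69), and did not pass with Guibi-tang (-0.33, adjusted p = 0.0596 in edgeR). None passed with Saengmaek-san or Okbyeongpung-san. The nuclear receptor NR4A1 fell with Menthae Herba (-1.36), Guibi-tang (-0.32) and Soyo-san (-0.56) and did not pass with Saposhnikoviae Radix (-0.27).

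ID genes and ATOH8 are known targets of BMP signalling, so lower BMP signalling is a candidate explanation. It was tested on 6 other targets, BAMBI, SMAD6, SMAD7, SMAD9, HEY1 and ID1, whose median log2 change at 500 against 20 averaged -0.198 over the 4 extracts (-0.198 with Menthae Herba, -0.205 with Saposhnikoviae Radix, -0.143 with Guibi-tang and -0.246 with Soyo-san). The direction may be in line with the explanation, but of the 6 only ID1 passed, and only with Menthae Herba (-0.41, adjusted p = 9.09e-04 in edgeR), so the value does not decide. Phosphorylated SMAD1 and SMAD5 in cells given 20 and 500 of these extracts would tell.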
